A study of Vitis vinifera with 3 samples.

How the data were processed

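Whole-genome bisulfite sequencing was used to measure cytosine methylation in berries of the grapevine cultivar Fujiminori. Bisulfite converts unmethylated cytosines so that they are read as thymine, and methylated cytosines stay cytosine. The labels describe 3 libraries, 1 per stage: first growth at 40 days after flowering, véraison at 65 days and maturity at 90 days. Per the labels' protocols, DNA was extracted with proteinase K and phenol, sheared by sonication, ligated to adaptors, treated with bisulfite and sequenced from both ends. The pooling of berries from several bunches is stated there for RNA only. BSMAP 2.73, an aligner for bisulfite reads, is named in the submitters' processing notes. The region caller, its coverage filter, the genome build and the gene annotation are not given in the sources used here.

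The authors deposited 9 tables of differentially methylated regions, 1 for each pair of stages and each of 3 cytosine contexts (CG, CHG and CHH, where H is A, C or T). Each row holds a region, the average methylation level of each library, a p-value and the gene model the region overlaps. Per the file headers, the deposited levels are fractions from 0 to 1, and they were multiplied to percent here. The authors rounded them, so levels move in steps of 1 percentage point. The deposited p-values are described in the files as a chi-square test statistic, but all lie at or below 0.00999823, so they were read as p-values of the authors' test between 2 libraries. No adjustment for multiple testing is stated with them. In 13 regions the p is listed as 0. The tables held 377997 regions of 41 to 1878 bp. No region was listed more than once in a table, and none had equal levels in both libraries.

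No read counts or coverage are in these tables, so the depth behind each level is unknown, and no interval was given for a level. Levels of 0% or 100% in short regions may therefore rest on few reads. Because regions were listed for differing, their levels are not averages of the genome. The plan expected counts or levels with gene parts and gene descriptions. The tables hold levels and gene-model overlap only, so the tests that need counts, promoters or exons were not run.

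Differences are always the later stage minus the earlier one. With 1 library per stage there was no test between stages, and every difference describes these libraries. The share of regions higher in the later stage was given with its exact Clopper-Pearson 95% interval, which covers counting error over regions only. Levels were summarised by the median and quartiles over regions. Fisher's exact test, two-sided, compared gene-model overlap between higher and lower regions of each table, and the direction of genes between contexts, each with Benjamini-Hochberg adjustment over 9 tests and a threshold of 0.05. Neighbouring regions are not independent, so these p-values describe regions of 2 libraries and are too small as statements about stages. Regions of different tables were called overlapping when they shared at least 1 bp. Overlap was set beside 50 random shifts, in which all regions of a chromosome moved by 1 random distance and wrapped around its end. These shifts, the densities along genes and the comparisons between contexts used the 19 numbered chromosomes.

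The tables name 9490 gene models with start, end and strand. Their identifiers were looked up in the reference gene list of assembly ASM3070453v1, which holds 29591 genes, and 0 matched. Gene symbols and functions were therefore not assigned, and the planned functional gene lists (flavonoid and stilbene synthesis, cell wall, sugars and acids, hormones, chromatin, transposons and others) were not analysed here. Region midpoints were counted in bins of 500 bp over 3 kb on each side of the listed gene models and in 5 equal parts of each model. Models that overlap no listed region are not in this set. Coordinates are those of the authors' tables. Their build is not given in the sources used here, nor whether starts count from 0 or 1.

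The rule for named genes was fixed before the data were examined. It took, per pair of stages and context, the 3 gene models with the largest increase and the 3 with the largest decrease. Ties were broken by the authors' p, then by number of cytosines, which was not available, and then by coordinate. For gene models known by identifier only, as here, the rule allowed fewer than 3 each way. Lists of 3 therefore go beyond it. Regions named for the smallest p, the greatest length or the densest window were chosen after their values were seen.

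The alternatives fixed before the data were examined kept regions with at least the median absolute difference of their table, regions with p at or under the largest p divided by 10, regions of at least the median length, or numbered chromosomes only. Others required an overlap of 0.5 of the shorter region, or replaced the difference by a log2 ratio with a pseudocount of 0.01 on the fraction. Joining overlapping regions of a table was added after seeing the data. The region statistics were tested on simulated data in 8 checks, and all 8 recovered the planted values within their set tolerance. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.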

Results

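DNA methylation was compared between berries at first growth, véraison (the onset of ripening, when berries soften and colour) and maturity, with 1 bisulfite sequencing library per stage. In plants, cytosines are methylated in the CG, CHG and CHH contexts, and CHH methylation, which has no symmetric partner on the other strand, has to be set anew after DNA replication. The values were average levels in the regions that the authors listed as differing between 2 libraries. There were no replicates, and the depth behind the levels is unknown.

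The comparison of véraison with first growth asked how methylation differed at the onset of ripening. CHH regions were almost all more methylated at véraison, whereas CG regions were mostly less methylated. Of 174174 CHH regions, 173545 were higher at véraison (99.6%, exact 95% interval 99.6 to 99.7%) and 629 were lower. Their median CHH level was 6% at first growth and 20% at véraison, with a median gain of 15 percentage points (quartiles 10 and 23). Of 4486 CG regions, 3643 were lower at véraison, and 18.8% (17.7 to 20.0%) were higher, or 9.61% among CG regions of at least the median length. The median CG level was 33% at first growth and 17% at véraison.

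CHG regions went both ways. Of 8000 CHG regions, 3236 were higher at véraison (40.5%, interval 39.4 to 41.5%) and 4764 were lower. Higher CHG regions had a median of 19% at first growth and 45% at véraison, and lower CHG regions had medians of 39% and 16%. CHH regions covered 14.0 Mb, against 1.74 Mb for CG and 1.59 Mb for CHG, and were shorter, with a median length of 63 bp against 352 bp for CG regions. The share of CHH regions that were higher lay between 99.5 and 99.7% on each of the 19 chromosomes. CHH regions were densest on chromosome 17, with 521 per Mb, and sparsest on chromosome 8, with 354 per Mb.

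In organelle DNA, where little cytosine methylation is usually found, CHH regions listed against first growth moved much less. The tables of véraison and maturity against first growth together held 17 entries for CHH regions in the chloroplast and mitochondrion, all higher in the later library. Both tables share the first growth library, and some entries overlap or repeat, so these are not numbers of distinct regions. Their median level was 1% at first growth and 2% later, and their median gain was 1 percentage point. The 8 chloroplast entries gained at most 2 percentage points, whereas the 9 mitochondrial entries had an upper quartile of 5 and a maximum of 12. In the mitochondrion, 11 of 13 CG entries and 18 of 19 CHG entries were lower in the later library, each with a median of 3% at first growth and 1% later.

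**Figure D1:**
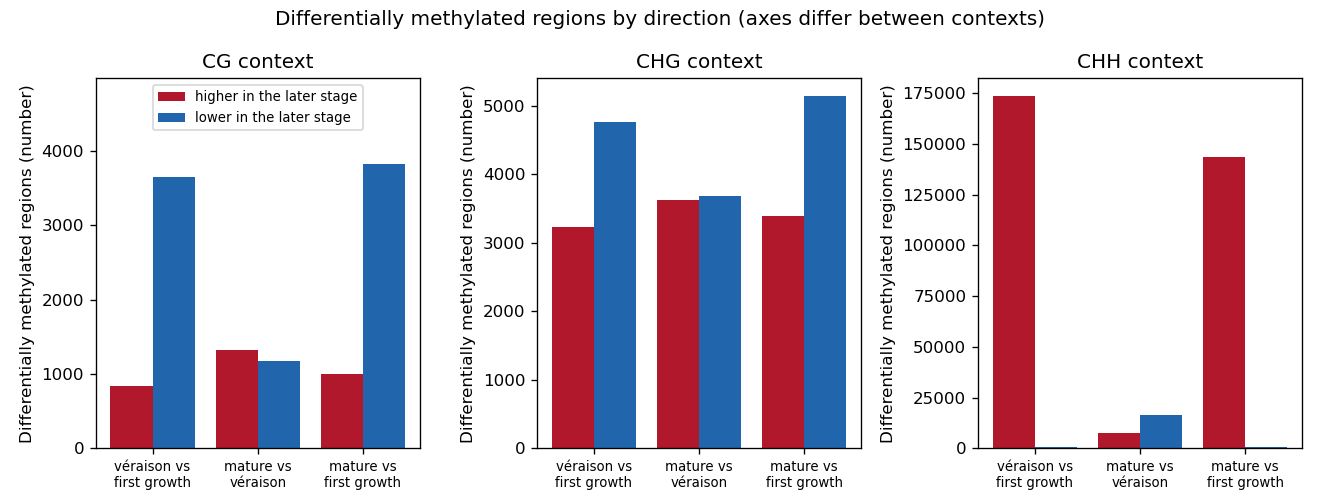
Number of differentially methylated regions (y axis, starting at 0, with a different scale for each context) per pair of stages (x axis), with red bars for regions higher and blue bars for regions lower in the later stage. In both pairs with first growth, higher CHH regions reach 173545 and 143505, while lower CHH regions number 629 and 836.

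The largest single differences within gene models at véraison crossed most of the range of levels. On chromosome 14, from 24867441 to 24867735 in the gene model VIT_14s0068g01090.t01, the CG level was 0% at first growth and 93% at véraison, with p = 0.000180599 in the authors' deposited table. On chromosome 5, from 10274188 to 10274537 in VIT_05s0051g00050.t01, the CG level was 20% at first growth and 96% at véraison. On chromosome 7, from 123502 to 123564 in VIT_07s0141g00170.t01, the CHH level was 88% at first growth and 0% at véraison, with p = 6.5253e-17 in the authors' deposited table. On chromosome 18, from 4881358 to 4881416 in VIT_18s0001g06500.t01, the CHH level was listed at 100% at first growth and 0% at véraison. For CHG, a region within a gene model on chromosome 17, from 14807141 to 14807225, went from 0% to 86%, and one on chromosome 2, from 3790479 to 3790541, from 88% to 4%. CHH levels rose from 0% to 100% in gene models on chromosome 14, from 23792910 to 23793024, on chromosome 1, from 9258592 to 9258644, and on chromosome 6, from 1993529 to 1993575.

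Other CG regions within gene models that were among the largest decreases lay on chromosome 9, from 7353557 to 7353774 (94% at first growth, 12% at véraison), and chromosome 3, from 9767400 to 9767463 (100% and 22%). The CG region with the smallest p was longer and lay within a gene model on chromosome 19, from 474148 to 474813. It had 77% at first growth and 19% at véraison, with p = 5.6904e-68 in the authors' deposited table. Outside gene models, a CHH region of 969 bp on chromosome 16, from 2523173 to 2524141, rose from 13% to 41%. A CHG region on chromosome 13, from 16241207 to 16241747, rose from 5% to 56%.

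Gene models held a smaller share of the CHH regions than of the CG or CHG regions, though more of them in number (17433, against 1290 and 3415). The contexts were not matched for region length, and the share of the genome in gene models was not computed. In the pair véraison and first growth, 10.0% of CHH regions (exact interval 9.87 to 10.2%), 28.8% of CG regions (27.4 to 30.1%) and 42.7% of CHG regions (41.6 to 43.8%) overlapped a gene model. Lower CHG regions overlapped gene models more often than higher ones, 45.5% against 38.5% (Fisher's exact test, adjusted p = 1.29e-09). Among CHG regions of at least the median length, this difference no longer passed the threshold (log2 odds ratio -0.07, adjusted p = 0.507 by the same exact test). CG regions showed the opposite order, with 34.2% of higher and 27.5% of lower regions in gene models (Fisher's exact test, adjusted p = 0.000184), but not among regions with at least the median absolute difference of the table (log2 odds ratio 0.25, adjusted p = 0.295). Of the few lower CHH regions, 18.1% were in gene models, against 9.98% of the higher ones (Fisher's exact test, adjusted p = 1.29e-09).

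Around the listed gene models, CHH regions were denser upstream than downstream. At véraison against first growth there were 0.613 CHH regions per kb in the 3 kb upstream, 0.193 per kb within gene models and 0.424 per kb in the 3 kb downstream. Models are listed because a region overlaps them, which raises the density within models. The flanks may be raised too, since a region that crosses the edge of a model can have its midpoint in a flank. The upstream to downstream ratio was 1.45, and the upstream density was the greater on 19 of 19 chromosomes, with ratios of 1.13 to 1.83. Density fell close to the gene start, from 0.682 per kb between 500 and 1500 bp upstream to 0.334 per kb in the nearest 500 bp. The same ratio was 1.47 for CHH regions of mature against véraison and 1.43 for mature against first growth, each above 1 on 19 of 19 chromosomes. CHG regions of véraison against first growth had a ratio of 0.94, and CG regions had 1.15.

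**Figure D2:**
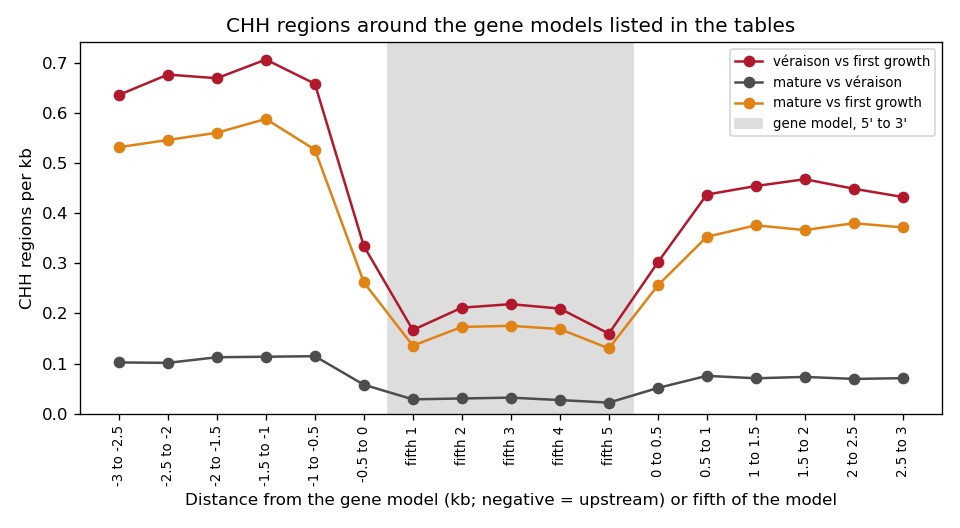
CHH regions per kb (y axis) in bins of 500 bp over 3 kb upstream and downstream of the listed gene models and in 5 equal parts of each model (x axis, grey area), with 1 line per pair of stages. For véraison against first growth, the upstream density of 0.613 per kb exceeds the 0.424 per kb downstream, and gene models hold 0.193 per kb. The density within models is raised because only models that overlap a region are listed.

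The comparison of maturity with véraison asked what differed during ripening itself. Far fewer CHH regions were listed, and most were lower at maturity. Of 23823 CHH regions, 16398 were lower at maturity and 31.2% (exact interval 30.6 to 31.8%) were higher. The lower CHH regions had medians of 31% at véraison and 8% at maturity, and the higher ones had 7% and 30%. The 2499 CG regions were more evenly split, with 53.1% (51.1 to 55.0%) higher at maturity, and the 7313 CHG regions were split almost equally, with 49.7% (48.5 to 50.8%) higher.

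The number of CHH regions between first growth and véraison was 7.31 times that between véraison and maturity, compared with 1.80 times for CG and 1.09 times for CHG. CHH regions covered 1.52 Mb between véraison and maturity. Lower CHG regions again overlapped gene models more often than higher ones, 51.4% against 42.7% (Fisher's exact test, adjusted p = 4.84e-13). The corresponding difference did not pass the threshold for CG regions, with 38.4% of higher and 36.3% of lower regions in gene models (Fisher's exact test, adjusted p = 0.301), or for CHH regions, with 11.1% and 10.4% (adjusted p = 0.132 by the same exact test).

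Within gene models, the CG level on chromosome 9, from 21159494 to 21159817, was 11% at véraison and 83% at maturity, and on chromosome 8, from 3919430 to 3920053, it was 87% and 23%. The latter had p = 9.24701e-27 in the authors' deposited table. The longest CHG region, on chromosome 6 from 12860519 to 12861841, lay in a gene model and rose from 4% to 25%. Among CHG regions in gene models, one on chromosome 13, from 787223 to 787280, fell from 94% to 0%, and one on chromosome 5, from 16592610 to 16592670, rose from 12% to 100%. A CHH region on chromosome 4, from 4499910 to 4499991, rose from 0% to 90%, and one on chromosome 6, from 5397383 to 5397426, fell from 100% to 0%. Outside gene models, a CHH region on chromosome 17, from 1356878 to 1357043, rose from 1% to 43%.

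The comparison of maturity with first growth spanned both periods. Its CHH regions were again almost all higher in the later library, with 143505 of 144341 higher at maturity (99.4%, exact interval 99.4 to 99.5%). The median CHH level was 6% at first growth and 21% at maturity. Of 4823 CG regions, 20.7% (19.5 to 21.8%) were higher at maturity, or 12.3% among those of at least the median length, and the median CG level was 33% at first growth and 17% at maturity. Of 8538 CHG regions, 39.7% (38.7 to 40.8%) were higher.

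Lower CHG regions overlapped gene models in 49.9% of cases and higher ones in 34.4% (Fisher's exact test, adjusted p = 7.18e-45). For CG regions the shares were 27.7% of lower and 37.0% of higher regions (Fisher's exact test, adjusted p = 2.79e-08), again not past the threshold among regions with at least the median absolute difference of the table (log2 odds ratio 0.19, adjusted p = 0.318). The chromosome 14 region in VIT_14s0068g01090.t01 was at 100% CG methylation at maturity, and the chromosome 19 region from 474148 to 474813 was at 22%. In VIT_07s0141g00170.t01, the CHH region from 123505 to 123564 was at 93% at first growth and 4% at maturity. CG levels were listed at 100% at first growth and 0% at maturity in gene models on chromosome 9, from 14824133 to 14824386, and chromosome 15, from 6907546 to 6907675. A CHG region in a gene model on chromosome 7, from 12876632 to 12876778, went from 82% to 0%, with p = 5.91532e-09 in the authors' deposited table.

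A small set of regions could be followed through all 3 stages, those with the same start and end in both tables against first growth. This choice favours places where véraison and maturity were alike, so the set does not show how alike these stages were elsewhere, where 23823 CHH regions were listed as differing between them. In 2632 such CHH regions, of the 174174 listed at véraison, the median level was 5% at first growth, 16.5% at véraison and 17% at maturity, and 92.6% of them differed by at most 5 percentage points between véraison and maturity. In 632 CG regions the medians were 36%, 13% and 13%, and 84.5% differed by at most 5 percentage points. In 263 CHG regions the medians were 34%, 19% and 18%.

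**Figure D3:**
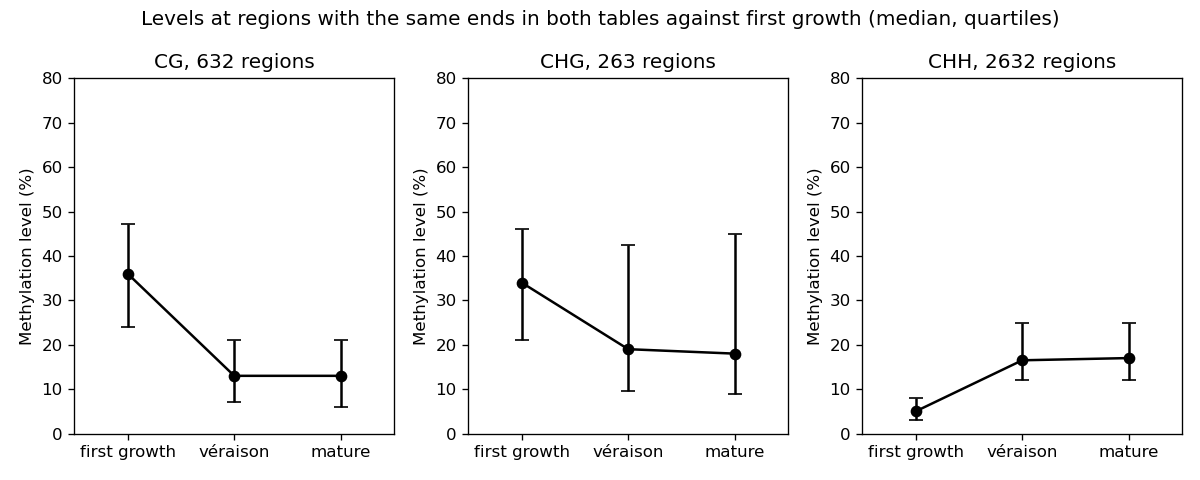
Methylation level in percent (y axis) at first growth, véraison and maturity (x axis), in regions with the same ends in both tables against first growth, with points for medians and bars for quartiles over regions. Median CHH levels are 5%, 16.5% and 17%, and median CG levels are 36%, 13% and 13%.

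The pairs of stages listed many of the same places. Of the CHH regions of véraison against first growth, 45.0% overlapped a CHH region of maturity against first growth, compared with 4.61% after random shifts. For CG and CHG the overlaps were 41.0% and 24.2%, compared with 0.780% and 0.746%. Overlapping pairs had the same direction in 99.9% (CHH), 97.8% (CG) and 97.2% (CHG) of cases, where the shares of higher regions in the tables alone give 99.1%, 68.3% and 51.9%. Both tables use the first growth library, so part of the excess in overlap and in direction may come from the shared library. Of the CHH regions lower at maturity than at véraison, 75.6% overlapped regions that were higher at véraison than at first growth, compared with 5.24% after random shifts. Of those higher at maturity than at véraison, 67.0% overlapped regions higher at maturity than at first growth, compared with 4.13%. Each of these pairs of tables also shares a library. A high level in the shared library alone would list a region in both with these directions, which the random shifts do not take into account. The overlaps therefore do not establish a gain followed by a loss.

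Between contexts, CG and CHG regions moved together. At véraison against first growth, 14.7% of CG regions overlapped a CHG region, compared with 0.978% after random shifts, and 98.9% of the 741 overlapping pairs had the same direction, where the shares of higher regions alone give 56.0%. The share was also 98.9% for maturity against véraison and 97.9% for maturity against first growth. Among gene models that went one way in both contexts, 82.8% of 238 had the same direction in CG and CHG at véraison (Fisher's exact test, adjusted p = 1.13e-16). The other pairs of stages also passed for CG and CHG, whereas the 6 tests that set CG or CHG against CHH did not (adjusted p from 0.494 to 1.0). Few gene models had lower CHH levels against first growth, so the tests of pairs with first growth could hardly have passed. The tests of maturity against véraison were not limited in this way. There, 50.5% of 91 gene models had the same direction in CG and CHH, and 50.8% of 258 in CHG and CHH.

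For CG and CHH regions, the share of overlapping pairs with opposite directions differed between the pairs of stages. Between first growth and véraison, 12.9% of CG regions overlapped a CHH region, compared with 13.0% after random shifts. Of 770 overlapping pairs, 679 combined a lower CG region with a higher CHH region, and 88.3% had opposite directions, where the shares of higher regions alone give 81.0%. Those shares ignore that lower CG regions overlapped CHH regions more often than higher ones did (15.2% against 3.09%). With nearly all CHH regions higher, the 88.3% is therefore no evidence of opposed change. Of the few pairs with a lower CHH region, 60 held a lower CG region and 1 a higher one. Pairs with a higher CHH region also held mostly lower CG regions, 679 against 30 higher. The 60 to 1 alone therefore does not show that CG and CHH fell together. Between véraison and maturity the overlap was 2.60%, compared with a mean of 1.82% and a maximum of 2.40% after random shifts, and 80.8% of the 73 overlapping pairs had the same direction, where the shares alone give 48.8%. Over whole gene models of that pair of stages, 50.5% of 91 had the same direction in CG and CHH (Fisher's exact test, adjusted p = 1.0). Between first growth and maturity, 79.7% of 763 pairs had opposite directions, where the shares alone give 79.0%. Here the pairs with a lower CHH region held a lower CG region in 111 cases and a higher one in 0. The pairs with a higher CHH region also held mostly lower CG regions, 608 against 44 higher. The share of overlapping CG and CHH pairs with the same direction was 20.3%, but 12.6% among the larger differences and 10.1% in the longer regions. What the shares alone give under those settings was not computed. At véraison, higher CG regions overlapped higher CHH regions in 2.97% of cases, compared with 10.3% after random shifts, and lower CG regions in 14.1%, within the random shifts (mean 13.6%, maximum 16.0%). For CHG the order was the other way round. Higher CHG regions overlapped higher CHH regions in 9.30% of cases, within the random shifts (mean 8.25%, maximum 9.40%), and lower CHG regions in 3.19%, compared with 8.85%. Overlapping CHG and CHH regions had the same direction in 71.9% of 623 pairs, where the shares alone give 40.5%. The values were 94.2% of 103 against 50.1% for maturity against véraison, and 68.7% of 556 against 39.9% for maturity against first growth. Against first growth, higher CHG regions overlapped CHH regions more often than lower ones did. The values were 9.34% against 3.99% at véraison and 7.72% against 3.70% at maturity. The shares alone ignore this, so 40.5% and 39.9% are too low as a baseline for the overlapping pairs. How much of the excess would remain was not computed. In all, 7006 gene models held a region in any context, and 125 held regions in all 3, for véraison against first growth. The latter number was 28 with at least the median absolute difference and 26 with at least the median length.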

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

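Joining overlapping regions was chosen after seeing the data, and the other alternatives were fixed before. Of 108 values of region number and of share higher, 67 stayed within 1.5 times or within the interval of the main value, 41 moved, and no share crossed 50% where the main interval excluded it. Counting each row changed nothing, because no region was listed more than once. Keeping numbered chromosomes only removed few regions and moved none of these values. These settings could hardly move a value, so the 67 overstates stability. Under the filters by difference, p and length, most of the shares moved. Of 291 other values, 187 stayed, 101 moved, and 3 tests of gene-model overlap no longer passed the threshold, as given with those results. Staying here meant lying within the main interval or 1.5 times the main value, keeping the sign of a log2 ratio, or keeping the outcome of a test. It thus includes changes of sign, such as the median CHG difference given below. Another is the log2 odds ratio of gene-model overlap for CHH regions of maturity against véraison (0.10, and -0.12 among the larger differences). The cause of the shifts was not tested, except that the number of regions falls by construction.

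With at least the median absolute difference, 2380 CG, 4053 CHG and 89255 CHH regions remained at véraison against first growth, 1284, 3693 and 12520 at maturity against véraison, and 2506, 4414 and 74310 at maturity against first growth. With at least the median length the numbers were 2248, 4017 and 87558, then 1251, 3660 and 12379, then 2413, 4276 and 73121.

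At véraison against first growth, the share of regions higher among those larger differences was 44.2% (CHG) and 99.6% (CHH). Under the stricter p it was 16.3% (CG), 38.6% (CHG) and 99.7% (CHH), and in the longer regions 9.61%, 37.0% and 99.8%. At maturity against first growth the larger differences gave 19.3%, 42.0% and 99.4%, the stricter p 18.6%, 37.9% and 99.5%, and the longer regions 12.3%, 33.2% and 99.6%. At maturity against véraison, CHG gave 47.7% among the larger differences and 47.8% in the longer regions, and CHH gave 30.5% under the stricter p and 28.1% in the longer regions. With overlapping regions joined, CHH gave 99.6% at véraison and 99.4% at maturity against first growth. The median CHG difference of maturity against véraison, where regions went both ways, was -5 percentage points in the main setting and 6 under the stricter p, but -23 among the larger differences, -8 in the longer regions and -6 with overlapping regions joined.

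The coverage minimum, the number of cytosines, the promoter and gene-body alternatives and the functional lists were not run, since the tables used here give no coverage, cytosine number, promoter overlap or gene names. No paired analysis was possible because each stage has 1 library. The unknown depth limits what can be said of single regions, including short ones at 0% or 100%.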

Other observations

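All tests of explanations in this part were chosen after the results were seen. The densest places differed between contexts. On chromosome 15, the window from 18.0 to 18.5 Mb held 31 CG regions of véraison against first growth, compared with a mean of 5.26 per window of 500 kb, and 3.23% of them were higher at véraison. The same window held 30 CG regions at maturity against first growth. CHG regions were densest on chromosome 16 from 4.5 to 5.0 Mb, with 39 regions against a mean of 9.38, and CHH regions on chromosome 18 from 18.0 to 18.5 Mb, with 475 against a mean of 204. These windows were picked for their counts.

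Single regions also stood apart. A chloroplast CG region from 97575 to 98054 was listed at 82% at véraison and 0% at maturity, with p = 1.42609e-06 in the authors' deposited table. The other organelle regions of that pair of stages moved by 1 percentage point. The depth of this region is unknown and an alignment error was not excluded, so the 82% is not established as methylation of chloroplast DNA. On chromosome 18, from 18535564 to 18536085, the CHH level was 1% at first growth and 2% at maturity, and the p was listed as 0 in the authors' deposited table. At véraison against first growth, 199 CHH regions on the chromosomes differed by at most 2 percentage points.

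The near-uniform gain of CHH methylation after first growth was set against incomplete bisulfite conversion in the later libraries, noise of a shallower first growth library, and a library or batch difference other than stage. Poorer conversion throughout a library would raise organelle DNA by about as much as the chromosomes, but the organelle CHH regions had a median gain of 1 percentage point, and those of the chloroplast at most 2, against a lower quartile of 10 on the chromosomes. Among the 9 mitochondrial entries, 6 gained 1 percentage point, but the upper quartile was 5 and the maximum 12, so a local effect there stays open. Random noise of a shallower first growth library would go both ways. At véraison, 99.6% of CHH regions were higher and 81.2% of CG regions were lower than in that library. These shares are the pattern to be explained, and the depth of the libraries is unknown. They were therefore no separate test of noise, which stays open. With 1 library per stage, a library or batch difference other than stage cannot be told apart from the stage, and a change in the fruit between first growth and véraison may be one explanation among these, untested.

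Higher CG regions overlapped higher CHH regions less often than lower CG regions did, while the lower ones overlapped them about as often as after random shifts. At véraison against first growth, higher CG regions were shorter, with a median of 234 bp against 384 bp, and more often in gene models. Without strata, the odds ratio of lower against higher CG regions was 5.35. Within 20 strata of length and gene-model overlap it was 3.34 (95% interval 2.35 to 5.31 over 1000 resamples of chromosomes). At maturity against first growth the odds ratio was 3.92 without strata and 2.48 (1.72 to 3.79) within them. These properties, as grouped here, could account for part of the difference and did not remove it. Differences of length within a stratum were not tested. Cytosine content and read mapping at these regions were not tested, and no biological explanation was tested.

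The excess of CHH regions upstream of gene models was set against 3 technical explanations. Around 5959 gene models listed in the CG or CHG tables, and so not chosen by CHH regions, the upstream to downstream ratio was 1.62 (interval 1.57 to 1.66). The intervals of these ratios cover counting error over regions only. They treat neighbouring regions as independent and leave out the spread between chromosomes, so they are too narrow. Around 5555 gene models with no other listed model within 6 kb it was 1.47 (1.43 to 1.51). Better read coverage of the upstream flank stays open, because the other contexts went apart. The CHG ratio was 0.94 (0.84 to 1.05) at véraison against first growth. At maturity against first growth it had an interval of 0.898 to 1.12. The CG ratio was 1.15 (1.02 to 1.29) and 1.28 (1.14 to 1.43). By chromosome, the ratio at véraison against first growth ran from 0.521 to 1.87 for CHG and from 0.826 to 1.72 for CG. It was above 1 on 5 of 19 chromosomes for CHG and on 15 of 19 for CG. Whether the CG or CHG ratio differs from 1 is therefore not settled by these intervals. At maturity against véraison, the ratio was 0.936 for CG and 0.879 for CHG, beside 1.47 for CHH. Cytosine content, transposons and unlisted neighbouring genes were not tested, so that CHH methylation varies more in upstream flanks may be kept only as one hypothesis of several.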
